A study of Mus musculus with 16 samples.

How the data were processed

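RNA from 16 whole mammary tumors of 4 rtTA-HER2d16 mice on the FVB/NJ strain was sequenced. Per the labels, polyadenylated RNA was used, libraries were made with an exon-capture kit (SureSelect XT Mouse All Exon) and read from both ends, and no treatment was given. Such a kit pulls down fragments that overlap annotated mouse exons, so the level of a gene also depends on how well its exons are captured. Each tumor was assigned to its mouse and letter from its title. The name of each deposited file also carries a code, XR for 3 libraries (525D, 527A and 527B) and XD for the other 13, whose meaning is not given in the sources used here.

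The deposited values are on a log2 scale, 1 column per tumor and 13312 genes, each named by symbol and Entrez number. The column header calls them normalized counts. Back-transformed as 2 to the power of the value, minus 1, they have an upper quartile of 991 to 998 in every library and a minimum of 0, so they were read as log2 of an estimated gene count scaled to an upper quartile near 1000, plus 1. That reading comes from the values and is not stated in the labels. The submitters' processing notes name STAR, Salmon 0.6.0 and the build mm10, without saying what each was used for. The annotation, the strand setting and the filter are not given in the sources used here. Every gene was above 0 in at least 12 libraries and 12757 genes were above 0 in all 16, so genes seen in fewer tumors were not analysed here. Reads that fit near-identical genes may have been split between them, which applies to keratins, ribosomal protein genes and the H2 genes.

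Depth was estimated from the step between low values of a library, which gives the value of 1 read. Totals came to 16.6 M to 22.5 M estimated reads per library, and 59.5% to 67.7% of the values under 30 were whole multiples of the step within 0.02 reads. The remainder were fractions, so no whole reads could be recovered for count-model tests. Capture and amplification make reads of a library dependent on each other, so the precision of a gene was taken from the spread between tumors and not from read numbers.

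The design, written before the data were examined, assumed counts and named a test for normalized values as its fallback. Since the values are log2 and whole reads could not be recovered, that fallback was used, limma with an intensity trend and robust variance moderation on the deposited values, with no further filter. Tests compared the 4 mice together (moderated F test on 3 coefficients), each mouse with the mean of the other 3, and the letters A to D with the mouse as a block. Benjamini-Hochberg adjustment was applied within each test, with a threshold of 0.05, and all tests were two-sided except the F tests. The spread between the 4 tumors of a mouse was the error, so these tests compare these 4 animals. For levels, the 4 tumors of a mouse were averaged first and the mean and SD taken over 4 mice. Differences are on the log2(value + 1) scale, which understates changes of genes near 0, and a gene listed at 0 is given as such because a 0 can be a failed estimate.

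Before the data were examined, 28 gene lists were fixed for epithelial states, receptor and pathway output, proliferation, hypoxia, immune and stromal cell types, antigen presentation, interferon response and tissues that could be carried along (fat, skeletal muscle, skin and blood). The score of a list is the mean log2 value of its measured members. Scores were compared between mice with an F statistic over all 2627625 assignments of the 16 tumors to 4 groups of 4, an exact test in place of the planned resampling. The direction of each list in each mouse was tested with camera of limma at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Similarity is the mean Pearson correlation of tumor pairs within mice minus that between mice, with the same exact enumeration. For 7 pairs of scores fixed beforehand, mouse means were removed and r and rho were tested over all 331776 permutations within mice. The same numbers of permutations served the pairs added later.

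Named genes followed a rule fixed beforehand. It takes a panel of 20 genes, of which 19 were measured and Erbb4 was not analysed here. It also takes the 12 genes of smallest p in the test over mice and, per mouse, the 3 largest rises and 3 largest falls on one side in all 4 tumors. For these, only genes past the threshold of their test count, and predicted genes and clone names are left out. Up to 3 members of a list past its score test and up to 5 genes past the letter test were also to be named, and none qualified. The rule's level limit, a mean log2 CPM of at least 0, was taken on estimated reads with a prior count of 2. An earlier run had taken it on the deposited scale, where every gene passes, and named Insyn2a in place of Npff until this was corrected. Members of lists given as examples, and gene families, were chosen after their values were seen.

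Symbols were checked against a RefSeq gene table through Entrez numbers (13305 matched). Coordinates, transcript length and GC content came from GENCODE M21 on GRCm38, the same build as mm10, and 13296 genes had a length, taken as the median over annotated transcripts. A smooth trend on length and GC (splines with 4 degrees of freedom, fitted on genes with a mean log2 value over 5) was removed per library as an alternative. Other alternatives were median-ratio size factors, library size alone, limma voom on estimated reads, a stricter filter (1 CPM in 8 libraries and 100 reads, 12496 genes), robust moderation off, the XR or XD code as a covariate or without XR libraries, the letter as a block, pseudocounts of 0.5 and 4, the skeletal muscle score as a covariate, and leaving out tumors or mice. Mouse labels were also reassigned to the tumors in 100 splits, the real one included.

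R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The gene tests were tested on simulated data made like the comparison of mouse 525 with the other 3 mice over 13312 genes. They recovered 57 of 100 genes changed by 1 log2 unit and 86 of 100 changed by 2, with 6 false calls, and the F test recovered 50 and 81, with 14 false calls. Simulated genes were drawn independently of each other, without the trends that genes of a real library share. Those recovery and false call counts therefore do not give the rates in these data. The score test gave p under 0.05 for 20 of 20 shifted lists and 14 of 280 unshifted ones. The human transgene is not among the genes of these tables and was not analysed here.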

Results

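Gene expression was measured by bulk RNA sequencing after exon capture in 16 mammary tumors of rtTA-HER2d16 mice. In this model an oncogenic splice form of the human receptor HER2, which lacks an exon next to the membrane-spanning segment, is switched on in the mammary gland by a tetracycline-controlled activator. Expression was induced at 1 month of age, and tumors then arose without treatment. Mice 525, 527, 531 and 555 each gave 4 tumors, lettered A to D, and tumor 525A is tumor A of mouse 525. Libraries held 16.6 M to 22.5 M estimated reads. The 10 genes of highest level took 8.94% to 18.9% of a library, and the single highest gene was a milk gene (Csn2 or Csn3) or an iron-binding protein (Trf or Ltf) in every tumor but 525A, where Mucl2, a mucin-like secreted protein, took 6.69%.

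The stated purpose was to describe the expression profile of tumors in this model beside human HER2-positive cancer and other HER2 mouse models. No normal gland and no other model were analysed here, so levels are given without a control. Luminal epithelial genes were high in every tumor. Krt8, a keratin of luminal cells, had a log2 level of 14.56 ± 0.22 (SD, n = 4 mice) at percentile 99.7 of all 13312 genes, and Krt18, its partner, had 14.04 ± 0.23. Epcam, an adhesion protein of epithelium, had 14.42 ± 0.09, and Cldn3, a tight junction protein, had 12.73 ± 0.22. The basal keratins were lower, with 9.05 ± 1.31 for Krt5 and 10.88 ± 0.48 for Krt14. Krt8 exceeded Krt5 in 16 of 16 tumors, by 5.51 ± 1.09 log2 units on average. The luminal list score exceeded the basal and myoepithelial score in 16 of 16 tumors, by 4.35 ± 0.14 (SD, n = 4 mice), from 3.26 in 525A to 5.72 in 525B. Krt5 itself ranged from 4.74 in 531B to 11.12 in 527C. These levels and scores were not corrected for transcript length or exon capture, so gaps between genes or lists depend on both.

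Mouse Erbb2, the gene of the HER2 receptor (Entrez 13866, chromosome 11, 98412470 to 98437716 on GRCm38), had a level of 10.21 ± 0.10 (SD, n = 4 mice), at percentile 79.6, from 9.92 in 527B to 10.71 in 531C. The human transgene was not analysed here, and whether its reads were counted under the mouse gene is not given in the sources used here. Erbb3, the partner receptor of HER2, had 11.35 ± 0.39, Egfr 9.92 ± 0.19 and Grb7, an adaptor beside ERBB2 in the human amplicon, 8.99 ± 0.16. The hormone receptors were lower, at 7.97 ± 0.21 for the estrogen receptor gene Esr1 and 5.86 ± 0.65 for the progesterone receptor gene Pgr. Mki67, a gene of dividing cells, had 10.88 ± 0.19 and Vim, an intermediate filament of mesenchymal cells, 11.82 ± 0.20. Ptprc, the common leukocyte antigen, stood at 9.19 ± 0.14 and Cd8a, a coreceptor of cytotoxic T cells, at 5.11 ± 0.73. Pdcd1, which encodes PD-1, stood at 3.67 ± 0.59 and Cd274, which encodes its ligand, at 6.99 ± 0.29.

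Among the 28 list scores (mean ± SD over 4 mice), milk and secretory differentiation was the highest at 13.52 ± 0.55, followed by MHC class I presentation at 12.40 ± 0.28 and luminal epithelium at 11.87 ± 0.11. MAPK pathway output scored 10.16 ± 0.12, interferon response 9.99 ± 0.36, immediate early and heat shock genes 9.69 ± 0.28, MHC class II presentation 9.67 ± 0.29, hypoxia 9.56 ± 0.14 and proliferation 9.18 ± 0.22. ERBB receptors and ligands scored 7.30 ± 0.10, the neighbours of Erbb2 in the human amplicon 8.34 ± 0.09, hormone-sensing epithelium 6.56 ± 0.37, basal and myoepithelial genes 7.52 ± 0.23 and mesenchymal transition 7.10 ± 0.12. Of the immune lists, macrophage genes scored 9.23 ± 0.16, neutrophil 5.97 ± 0.25, immune checkpoint 5.12 ± 0.36, dendritic cell 4.37 ± 0.20, T cell 4.01 ± 0.42, cytotoxic and NK cell 3.78 ± 0.43 and B cell 2.60 ± 0.38. The B cell score rests on 5 of 10 listed genes, and the cytotoxic and NK cell score on 5 of 13. Fibroblast and matrix genes scored 9.28 ± 0.16, endothelium 7.53 ± 0.11, skin keratinocyte 6.48 ± 0.63 and brown adipocyte 5.09 ± 0.62. The widest ranges between tumors were those of the skeletal muscle, adipocyte and red blood cell scores. The adipocyte score (5.35 ± 1.28) ran from 1.97 in 531B to 8.02 in 527D, the red blood cell score (9.16 ± 0.52) reached 13.48 in 531A, and the skeletal muscle score (6.95 ± 1.81) ran from 2.33 in 531A to 12.21 in 525B. Scores average genes of unlike capture and length, so the order of the lists depends on both. They rank tumors for one list and do not measure cell shares.

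**Figure D1:**
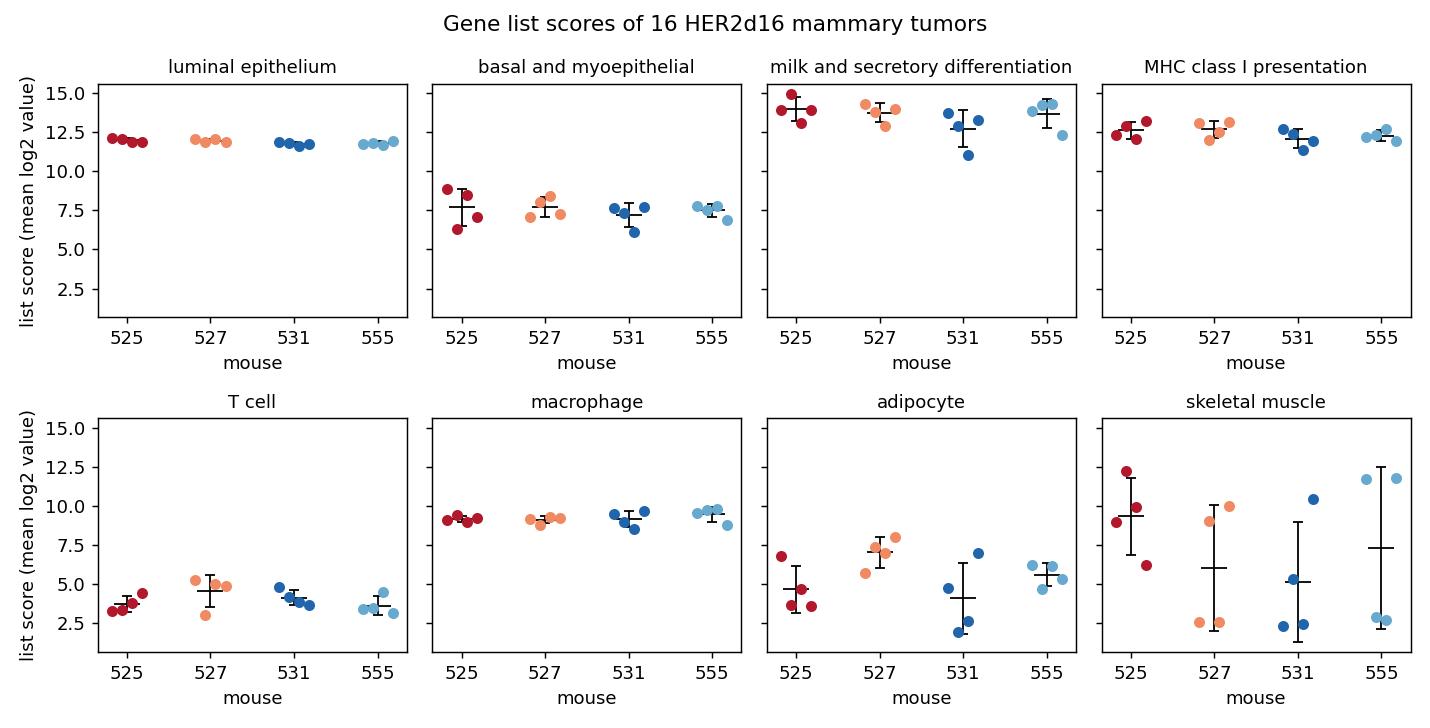
List scores (y axis, mean log2 value of the measured members) by mouse (x axis) for 8 of the lists, with 1 point per tumor, coloured by mouse, and black bars for the mean and SD over the 4 tumors of a mouse. Luminal scores lie between 11.62 and 12.13 in all 16 tumors, while skeletal muscle scores spread from 2.33 to 12.21.

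The mouse is the only labelled group in the series, so the 4 mice were compared with the spread between tumors of a mouse as the error. By limma on the deposited values, mouse 525 alone had genes called against the other 3. Capn12, a calpain protease, was 2.45 ± 0.41 log2 units (SE) higher in its 4 tumors than in the other mice, and Malat1, a nuclear noncoding RNA, 1.80 ± 0.26 higher. Cntd1, a gene of meiotic recombination, was 1.15 ± 0.19 higher and Chrnb2, a nicotinic receptor subunit, 0.91 ± 0.14 higher. Mfsd9, a transporter-like membrane protein, was lower, at −1.88 ± 0.28, as were Soga1 at −1.20 ± 0.20 and Spint1, an inhibitor of epithelial serine proteases, at −0.48 ± 0.07 (limma adjusted p = 0.0147 for each of these 7 genes). Timm10b, a mitochondrial import protein (0.89 ± 0.15), Shfl, an interferon-induced antiviral gene (0.88 ± 0.15), Leng1 (0.78 ± 0.13), Krtcap2, a subunit of the N-glycosylation complex (0.70 ± 0.12), and Rpl22, a ribosomal protein (0.56 ± 0.09), were also higher at the same adjusted p. These 12 genes had the smallest p in the moderated F test over the 4 mice (adjusted p = 0.0295 for each). Once a trend on transcript length and GC was removed, Timm10b went to 0.22 ± 0.08 and was no longer called (limma adjusted p = 0.0943). Krtcap2 went to 0.22 ± 0.06 (adjusted p = 0.0403) and Malat1 to 1.06 ± 0.22 (adjusted p = 0.0273), while the other 9 moved by less than 1.5 times and stayed called. In the 9 that were higher in mouse 525 the mean was highest in mouse 525, then 527, 555 and 531. Single tumors overlapped, as Capn12 was 10.35 in 527B and 10.03 in 525A, and Malat1 was 14.10 in 527B and 13.85 in 525C. Capn12 lies on chromosome 7 (28881422 to 28893563), Malat1 on chromosome 19 (5795690 to 5802672) and Mfsd9 on chromosome 1 (40772038 to 40790687), all on GRCm38.

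In all, 2218 of 13312 genes differed between mouse 525 and the mean of the other 3 mice, 1194 higher and 1024 lower (limma, adjusted p under 0.05). Of these, 44 were higher and 160 lower by over 1 log2 unit. The F test over the 4 mice called 1410 genes. The naming rule ranked only called genes with a mean log2 CPM of at least 0 and all 4 tumors on one side. Within those limits the largest rises in mouse 525 were those of Capn12, Kbtbd8 (2.00 ± 0.64 SE, adjusted p = 0.0447) and Npff, which encodes a neuropeptide precursor (1.93 ± 0.47, adjusted p = 0.0178). Some uncalled genes rose more, as the skeletal muscle list had a median difference of 3.34 in mouse 525 without a called member. Kbtbd8 kept its call in 10 of 29 alternatives (adjusted p from 0.0184 to 0.200), 5 of them among the 16 that leave out 1 tumor (527B, 527C, 531A, 531B or 555D). Npff kept its call in 24 of 29 (adjusted p from 0.0142 to 0.185). It was no longer called without 525B or 525D, and without either tumor no gene at all was called in mouse 525. With the trend on length and GC removed neither was called, at 2.13 ± 0.66 for Kbtbd8 (adjusted p = 0.0700) and 1.29 ± 0.42 for Npff (adjusted p = 0.0807). Within the same limits, the largest falls were in genes listed at 0 in some tumors of the mouse. Zfp229, a zinc finger gene, was listed at 6.92, 0, 5.92 and 0 in tumors A to D against 6.18 to 8.04 in the other 12 (adjusted p = 0.0193). Syne3, which encodes a nuclear envelope protein, was listed at 3.93 in 525A and at 0 in the other 3 tumors, against 3.58 to 6.47 elsewhere (adjusted p = 0.0147). Rsc1a1 was listed at 0, 0, 4.51 and 3.34, against 4.94 to 6.98 elsewhere except for 0.00 in 555C (adjusted p = 0.0232). Scaling by library size shifted the median of all genes in mouse 525 from 0.02 to −0.09, and the calls then split into 438 higher and 1449 lower. Voom split them into 477 higher and 1266 lower.

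Of 278 measured genes in the 28 lists, 11 differed between the mice and, in mouse 525, 8 were higher and 6 lower. Of all 13312 genes, 1410 differed between the mice, and 1194 were higher and 1024 lower in mouse 525. List genes were thus called less often than genes at large. The examples here were chosen after their values were seen. The F test over mice called no gene with the length and GC trend removed, nor with the XR code or the muscle score as a covariate. None of the F test calls below held in those settings. Erbb3 was the only panel gene called, from 10.85 ± 0.12 in mouse 525 to 11.76 ± 0.45 in mouse 531 (SD, n = 4 tumors each, limma F test adjusted p = 0.0478). Areg, a ligand of the EGF receptor, ran from 6.66 ± 0.97 in mouse 555 to 8.84 ± 0.67 in mouse 527 (limma adjusted p = 0.0295). Both are ERBB receptors and ligands, of which 2 of 11 were called, and 2 adjusted over the list alone. In the MAPK output list 3 of 12 were called, and 4 adjusted over the list alone. Dusp4, a phosphatase that acts on MAP kinases, was lowest in mouse 525 at 8.18 ± 0.51 and highest in mouse 531 at 10.12 ± 0.77 (limma adjusted p = 0.0403). Phlda1 was highest in mouse 525 at 12.79 ± 0.24 (limma adjusted p = 0.0295), so members went both ways. The other called members were Spry4, Pgap3, Wnt4, P4ha1, the interferon-induced Isg15 (adjusted p = 0.0424) and the skin keratins Krt10 (adjusted p = 0.0299) and Krt15 (adjusted p = 0.0412). Adjusted over the list alone, the calls came to 1 for the amplicon neighbours, 2 for hormone-sensing epithelium, 1 for hypoxia, 0 for interferon response and 2 for skin. The luminal list had no member called over mice and 2 called in mouse 525, Elf3 and Elf5, and 0 adjusted over the list alone.

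Genes with short transcripts made up most of the rise in mouse 525. Median transcript length was 1276 bases for the genes called higher, 4421.5 for those called lower and 2739 for the rest. Genes were divided by length into 4 classes of like size. In the shortest class, 820 of 3324 genes were higher and 37 lower, and in the longest class 76 of 3323 were higher and 618 lower. Cytosolic ribosomal protein genes, which are short, were higher in 69 of 81 cases with a median of 0.59 log2 units, which was 0.57 with median-ratio factors and 0.47 with library size alone. Mitochondrial ribosomal protein genes were higher in 53 of 78 cases and subunits of respiratory complex I in 32 of 47. With a trend on length and GC removed, the genes called higher came to 6 of 81, 16 of 78 and 3 of 47 in these 3 families, with medians of 0.03, 0.11 and 0.11, against 330 of all 13312 genes. Zinc finger genes were lower in 30 of 339 cases as deposited, against 1024 of all 13312 genes. With the trend removed they were lower in 22 of 339, against 427 of all 13312. The families were chosen after their values were seen, and their genes are not independent. The rank correlation across genes of a library's deviation with length ran from −0.56 in 525D to 0.56 in 531D, and genes are not independent replicates for it. It was negative in all 4 tumors of mouse 525 and in 527A, 527B, 527C and 555D. Skeletal muscle genes were also at a high level in mouse 525, with a list score of 9.33 ± 2.47 (SD, n = 4 tumors) against 6.05 ± 4.04, 5.14 ± 3.81 and 7.29 ± 5.16 in mice 527, 531 and 555, a difference that passed or not by setting. The limma camera adjusted p was 0.0733 as planned, 0.0457 with the letter as a block, 0.0280 with the trend removed and 0.944 with an estimated correlation, and with fry it was 0.651.

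The count for mouse 525 fell to 0 without 525B, without 525D, without the 3 XR libraries or without the 4 libraries of highest muscle score (525B, 531D, 555A and 555D), and to 757 once a trend on length and GC was removed. With the muscle score as a covariate it was 1674, and with the XR code 1898. The count over the 4 mice was 0 without any 1 of 525B, 525D, 527C, 531D, 555A, 555B or 555C, 586 without 527A, 868 without 531B, 457 without 531C and 2853 without 527D, and it was also 0 with the XR code or the muscle score as a covariate, without those XR or muscle libraries, or after the trend was removed.

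**Figure D2:**
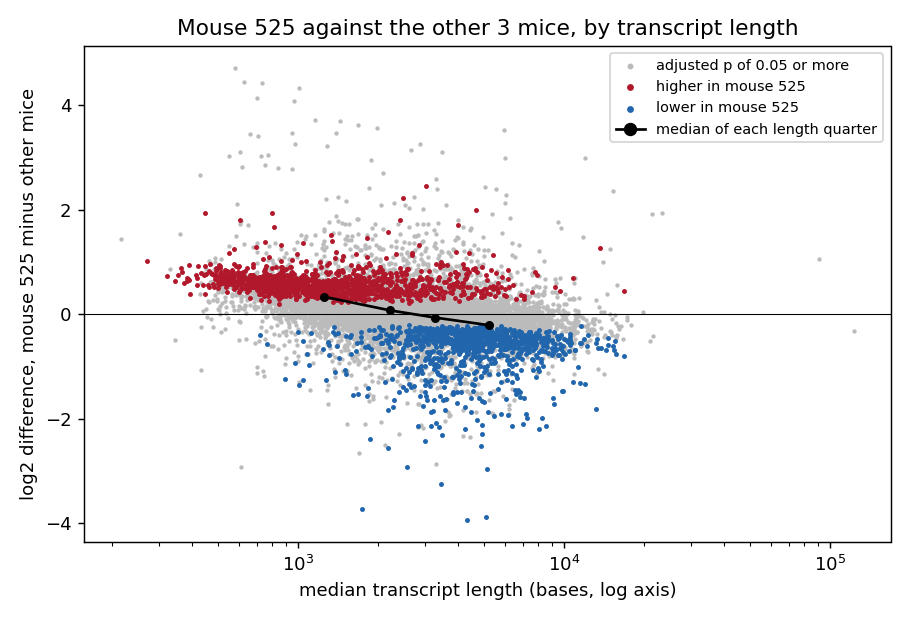
Log2 difference between mouse 525 and the mean of the other 3 mice for each gene (y axis) against median transcript length in bases on a log axis (x axis), with genes called higher or lower marked and the median of each of 4 length classes as black points. The medians step down from 0.34 in the shortest class to −0.21 in the longest.

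In mice 527, 531 and 555 no gene passed the threshold, and gene groups are given by list. Camera of limma with a preset correlation called 15 of 112 tests (28 lists in 4 mice), all given here, and every one of the 15 was lost with an estimated correlation (adjusted p = 0.944 for each) and with fry, which called 0. The adipocyte list stood higher in mouse 527 than in the other mice by a median of 1.92 log2 units (camera adjusted p = 9.98e-09), and proliferation by 0.34 (adjusted p = 1.36e-07), both lost with an estimated correlation. Interferon response was higher by 0.42 (adjusted p = 0.00166), T cell genes by 0.94 (adjusted p = 0.00747, with 527B at a score of 3.02 and the other 3 tumors at 4.91 to 5.29) and MHC class I presentation by 0.42 (adjusted p = 0.0178), each lost in the same way. Skin keratinocyte genes (0.50, adjusted p = 0.0116) and hormone-sensing genes (0.63, adjusted p = 0.0351) were higher there too, and hypoxia genes lower (median −0.13, adjusted p = 0.0113), again only at the preset correlation. In mouse 531 the milk list was lower by a median of −1.08 (adjusted p = 0.0113), interferon response by −0.56 (adjusted p = 0.0181), adipocyte genes by −1.74 (adjusted p = 0.0290) and skin genes by −0.79 (adjusted p = 0.0418), none of them with an estimated correlation. In mouse 555 proliferation was lower (−0.36, adjusted p = 4.25e-05) in 3 tumors with scores of 8.63 to 8.74, while 555D had 9.62, and macrophage genes (0.30, adjusted p = 0.0113) and immediate early and heat shock genes (0.23, adjusted p = 0.0322) were higher, all at the preset correlation only. At the preset correlation, adipocyte and proliferation genes in mouse 527 and proliferation in mouse 555 kept their calls without any 1 tumor. The other 12 calls were lost without 527D. The estimated correlation was 0.711 for adipocyte and 0.840 for proliferation genes, so the kept calls rest on the preset value of 0.01. All 4 in mouse 531 were lost without 531C (camera adjusted p from 0.0727 to 0.256). Leaving out 531C also ended the hormone-sensing and MHC class I calls in mouse 527. In mouse 555 it ended the macrophage and the immediate early and heat shock calls. T cell, interferon, MHC class I and hormone-sensing genes in mouse 527 were lost without 527A, and 1 to 3 calls were lost without 525D, 531B, 531D, 555B, 555C or 555D. The number of calls was 27 without 527B, 26 without 527C, 3 without 527D, 24 without 531A, 7 without 531C and 24 without 555C.

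By single genes, limma called 0 in mouse 527 (569 at unadjusted p under 0.05), 0 in mouse 531 (3502 at unadjusted p under 0.05, smallest adjusted p = 0.0621) and 0 in mouse 555 (1171 at unadjusted p under 0.05), and limma voom called 0, 1 and 0. Without tumor 527D the count in mouse 531 was 2344, with 983 higher and 1361 lower, and it was 4 without 531D, 1 without 525C and 1 without 531B, while mouse 527 had 1 gene without 527B and 2 without the XR libraries, and mouse 555 had 2 without the 4 libraries of highest muscle score.

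Compared as 1 score per tumor, no list differed between the 4 mice after adjustment. The skin keratinocyte score, of 3 measured genes (Krt10, Krt15 and Sbsn), was 7.09 ± 0.32 in mouse 527, 6.90 ± 0.30 in mouse 525, 6.20 ± 0.28 in mouse 555 and 5.73 ± 0.65 in mouse 531 (SD, n = 4 tumors each, exact p = 0.00206, adjusted p = 0.0578). Luminal scores ran from 11.76 ± 0.10 in mouse 531 to 11.99 ± 0.12 in mouse 525 (n = 4 tumors each, exact p = 0.0400, adjusted p = 0.556). The exact test thus called 0 of 28 lists, with these 2 at unadjusted p under 0.05. With the median of members in place of the mean both the luminal and the skin list passed (exact test, adjusted p = 0.0408 for each), and without 531A the skin list passed (exact test, adjusted p = 0.00522).

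Tumors with the same letter were compared across mice, since the labels do not say whether a letter marks the same gland. No gene differed between letters A to D with the mouse as a block by limma (168 at unadjusted p under 0.05, smallest adjusted p = 1.0), and limma voom also called 0 (258 at unadjusted p under 0.05). Genes such as Krt8, Krt5, Erbb2 and Acta1 had an adjusted p of 1.0 as well. Without the 4 libraries of highest muscle score the count was 2.

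Whole profiles of tumors from 1 mouse were hardly closer to each other than to tumors of other mice. The mean Pearson correlation was 0.938 over 24 pairs within mice and 0.933 over 96 pairs between mice, a difference of 0.00527 (two-sided exact p = 0.122). The closest pair, 531D and 555A (r = 0.979), came from different mice, and the farthest pair was 525B and 531C (r = 0.868). With Spearman correlation the difference was 0.00660 (exact p = 0.0305). It was 0.00936 without 531D (exact p = 0.0156), 0.00752 without 527D (exact p = 0.0484), 0.00201 without 525B and 0.00330 without 555A. It was 0.00292 with the length and GC trend removed (exact p = 0.363) and 0.00855 over the 2000 genes of highest variance (exact p = 0.520).

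Relations between immune, epithelial and signalling scores were computed for 7 pairs, with mouse means removed. Tumors with a higher T cell score for their mouse also had a higher score for MHC class I presentation, the genes that display peptides to cytotoxic T cells (r = 0.743, exact permutation p = 0.00271, adjusted p = 0.0190, and rho = 0.771, exact permutation p = 0.00190, adjusted p = 0.0133, 16 tumors). Within mouse 527 the T cell score was 3.02 and the MHC class I score 11.97 in 527B, against 5.29 and 13.04 in 527A. Without 527B and 555C, the tumors farthest from the median of the mouse-centred T cell score, r was 0.631 (exact permutation p = 0.0894, adjusted p = 0.626), so the call rests on those tumors, among others, while r kept its sign. Among the 13 XD libraries r was 0.574 (exact permutation p = 0.0783, adjusted p = 0.274), the 3 XR libraries are too few for a value of their own, and the adjusted p for r was 0.0581 without 525D, 0.0605 without 527A, 0.105 without 527B, 0.0562 without 531A and 0.0781 without 555C.

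The other 6 pairs did not pass. The T cell score had r = 0.419 with the macrophage score (exact permutation p = 0.107, adjusted p = 0.249, rho = 0.365), −0.146 with proliferation (adjusted p = 0.711, rho = −0.229), −0.00922 with the luminal score (adjusted p = 0.977, rho = −0.209) and −0.198 with fibroblast and matrix genes (adjusted p = 0.621, rho = −0.176). Erbb2 had r = 0.493 with MAPK output (exact permutation p = 0.0750, adjusted p = 0.249, rho = 0.374) and 0.436 with proliferation (adjusted p = 0.309, rho = 0.247). T cell and macrophage scores passed without 531D (r = 0.603, adjusted p = 0.0491) or without the 4 libraries of highest muscle score (r = 0.706, adjusted p = 0.0344), and Erbb2 with MAPK output passed under library size scaling (r = 0.707, adjusted p = 0.0195).

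**Figure D3:**
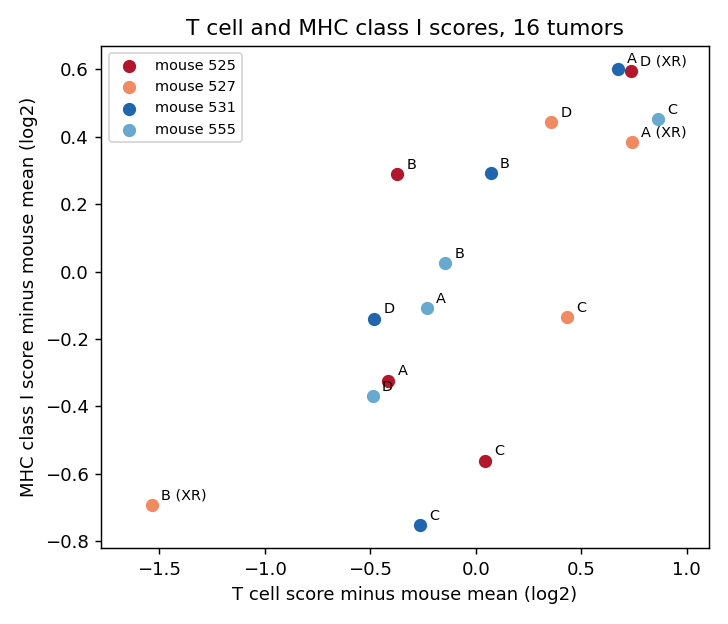
MHC class I presentation score (y axis) against T cell score (x axis), both in log2 units with the mean of the mouse removed, 1 point per tumor, labelled by its letter and by XR where it has that code, with mice told apart as in the legend. The points rise together (r = 0.743), with 527B farthest to the left.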

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

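The tests of T cell and MHC class I scores, of ribosomal protein genes and of the genes still called after the length trend was removed were chosen after their results were seen. The other tests here were written before their values were computed, though the length trend, the XR codes and the scores had been looked at by then. Within the 4 tumors of a mouse, a tumor is listed where its gap to the nearest of the others exceeds the critical value of Dixon's test at the 1 in 20 level. Chance does so in about 1 in 20 groups, and here it happened in 16 of 256 tests (6.25%), 5 of them in tumor 555D.

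Tumor 555D stood above the other 3 tumors of its mouse in the proliferation score (9.62, others 8.63 to 8.74), in Mki67 (11.48, others 10.29 to 10.48) and in Capn12 (9.69, others 8.06 to 8.33). It stood below them in Ptprc (8.60, others 9.54 to 9.68) and Zfp229 (6.59, others 7.18 to 7.23). Tumor 555C was high in the interferon score (10.34, others 9.59 to 9.72) and the cytotoxic and NK cell score (3.74, others 3.22 to 3.28). In mouse 527 the T cell score of 527B was far below the rest (3.02, others 4.91 to 5.29). In mouse 531, Ptprc was low in 531C (8.45, others 9.37 to 9.55) and Timm10b high in 531A (9.96, others 9.46 to 9.52). The score of the neighbours of Erbb2 in the human amplicon was high in 531D (8.85, others 8.01 to 8.09) and low in 525D (7.87, others 8.56 to 8.70), and that list holds Tcap, which is also a muscle gene. In mouse 525, the hypoxia score was low in 525A (9.38, others 9.76 to 9.80), Leng1 was high (9.17, others 8.61 to 8.65) and Mfsd9 low (2.82, others 3.79 to 3.86) in 525B, and Syne3 was listed at 3.93 in 525A and at 0 in the others.

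The 2218 genes called in mouse 525 were weighed against a length and GC trend, the XR code and carried-in muscle. Removing the trend took their median absolute difference to 0.566 times its value, between the bounds set beforehand (0.5 and 0.75). That test was therefore undecided. The median went from 0.55 to 0.23 for the genes called higher and from −0.52 to −0.38 for those called lower. Of all 2218 genes, 28.1% or 624 genes (269 higher and 355 lower) were still called in the same direction. That share does not decide whether the trend was the whole cause. Its bound of 5% was set after the count was seen, and a trend removed only in part would also leave calls. The other 1594 genes lost their calls as their median went from 0.51 to 0.22 and its median SE from 0.14 to 0.10, which is no test since they were picked for that loss, while cytosolic ribosomal protein genes went from 0.59 to 0.04 (0.0609 times), so the trend is a candidate source of the rise of that family. Leaving out the XR libraries left the median difference at 1.03 times its value (0.54 to 0.56). The calls ended without XR, though, with a count of 0 against 2218. Beforehand, a count under 0.5 times the main one was set as the mark of an XR cause. A median of 0.75 times or more was set as the mark against it. Both marks were met, so the test does not decide on the XR code. In that fit the median SE went from 0.14 to 0.16 and residual degrees of freedom from 12 to 9. Leaving out 525D alone, an XR library, ends the calls as well, as does leaving out 525B. With the muscle covariate the median was 1.04 times its value, past the bound of 0.75 set beforehand. That fit called 1674 genes, 1614 of them among the 2218, which argues against muscle as scored being the whole cause. Without the 4 libraries of highest muscle score, 525B among them, the median was 0.822 times and no gene was called. A real difference between the animals stays open and was not tested, since a mouse and its handling cannot be separated here.

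Chance was weighed by redrawing the mouse labels in 100 splits, the real one included. For mouse 525, 2 of the 100 gave as many genes (real 2218, highest other 2702), and over the 4 mice 1 of the 100 did (real 1410, highest other 351). Counts as large thus came up in fewer than 1 in 20 of the drawn splits. With 100 splits drawn that share is known only roughly, so chance is not excluded for mouse 525. Counting the largest of the 4 groups of each split, a check added after the count was seen, 2 of the 100 reached 2218 as well. Other random splits gave 1378, 1377 and 1184 genes in 1 of their groups. The split that gave 2702 genes put 525B, 525D, 527A and 527B together, which takes in all 3 XR libraries. XR against XD with the mouse in the model called 0 genes by limma (466 at unadjusted p under 0.05, smallest adjusted p = 0.942). The XR code occurs in only 2 mice, so that count does not show that the code had no effect. Across genes, the XR difference had a rank correlation of −0.473 with transcript length, and the mouse 525 difference had −0.560. Genes are not independent replicates for these correlations. With the XR code as a covariate mouse 525 kept a count of 1898 and the test over mice fell to 0. For mice 527, 531 and 555, 100 of 100 splits gave as many genes as the real count of 0 (highest other 2702), and for the letters 100 of 100 reassignments within mice did (real 0, highest other 39), but a real count of 0 fixes that outcome, so these splits decide nothing.

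T cell and MHC class I scores moved together (r = 0.743), with 527B low in both. Removing the length trend left r at 0.763, which argues against that trend. The leukocyte gene Ptprc went with the MHC class I score (r = 0.764, exact permutation p = 0.000971, adjusted p = 0.00194) and the interferon score went with the T cell score (r = 0.814, exact permutation p = 0.00178, adjusted p = 0.00267) and the MHC class I score. The macrophage score also went with the MHC class I score (r = 0.624, exact permutation p = 0.0171, adjusted p = 0.0206). The B cell score did not pass (r = 0.267, exact permutation p = 0.410). It rests on 5 of 10 listed genes at a low mean of 2.60, so it decides little. T cell with macrophage scores did not pass either (r = 0.419, adjusted p = 0.249). A shared interferon response may therefore contribute, and whether leukocytes of every kind do stays open.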

How the results depend on the processing

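The length and GC trend, muscle and pseudocount settings were chosen after the data were seen, and median-ratio factors were added for similarity and relations. Count-model tests with their normalizations, the planned main design, were not run because whole reads could not be recovered (voom was run on estimated reads), and the planned run without a filter equals the reported one. The cause of a change was not tested unless given.

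Genes over the 4 mice (1410) numbered 924 with library size alone, 881 with voom, and 0 with the XR covariate, without the XR libraries, with the length and GC trend removed, with the muscle covariate and without the 4 libraries of highest muscle score. Leaving out mouse 527 gave 2162, and leaving out mouse 525, 531 or 555 gave 0. Mouse 525 (2218) fell to 0 without the XR libraries and without those 4 muscle libraries, where fewer libraries remain, and to 757 with the trend removed. Its count was 1674 with the muscle covariate and 1898 with the XR covariate. Mouse 527 had 2 without XR libraries, mouse 531 had 1 with voom, and mouse 555 and the letters had 2 each without the 4 muscle libraries. Leaving out 1 tumor, counts ran from 0 to 2853 over the mice, 0 to 2530 for mouse 525, 0 to 1 for mouse 527 and 0 to 2344 for mouse 531, with 0 throughout for mouse 555 and the letters.

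The letter as a replicate block left 2 genes over the mice and 1580 for mouse 525, and gave 20 camera calls. Letters did not pair the tumors, as 6 of 24 same-letter pairs correlated over 0.1 (mean −0.0525, range −0.364 to 0.306) and 1 of 16 tumors correlated best with its own letter.

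The luminal minus basal score was 4.19 with the median over tumors (4.35 with the mean). List tests called 2 with the median of members and 0 to 1 without 1 tumor. Camera calls (15) were 0 with an estimated correlation, 0 with fry and 3 to 27 without 1 tumor. Similarity was 0.00660 with Spearman, 0.00292 with the trend removed and 0.00201 to 0.00936 without 1 tumor. Relations past the threshold (1) were 2 with library size, 2 without the 4 muscle libraries, 0 without XR libraries, 0 without the 2 farthest tumors and 0 to 2 without 1 tumor. For T cell with MHC class I, r was 0.574 without XR libraries, 0.631 without the 2 farthest and 0.676 to 0.809 without 1 tumor. Values near 0 changed sign. T cell with proliferation was 0.0172 without the 4 muscle libraries, and T cell with luminal was 0.00898 with median-ratio factors, 0.0553 with pseudocount 0.5, 0.0707 with the trend removed, 0.157 without the 4 muscle libraries and −0.283 to 0.143 without 1 tumor (0.0805 without 525A, 0.0227 without 525B, 0.109 without 525D, 0.0415 without 527D, 0.143 without 555C, 0.120 without 555D). Of 522 alternatives for the 18 named gene results, 326 kept the call, 196 lost it and 0 changed sign. Panel levels moved by less than their SD without any 1 tumor. At 16.6 M to 22.5 M estimated reads, the stricter filter on low values gave 1472 genes over the mice and 2292 for mouse 525, and no table ties a result to depth otherwise.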

Other observations

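The 6 relations given here and the test on further muscle genes were chosen after the values were seen, while the test of the muscle range was written before its result. Tumor 531C stood at the low end of many gene groups. It had the lowest score of the 16 tumors in 12 of 28 lists, among them luminal epithelium (11.62), milk and secretory differentiation (11.06), macrophage (8.53), MHC class I presentation (11.32), MHC class II presentation (8.41) and interferon response (8.65). It had the highest level of Erbb2 (10.71), Erbb3 (12.36) and Grb7 (9.36) and the highest MAPK output score (10.61). Krt5, a basal keratin, was 5.43 in 531C and 4.74 in 531B, against 8.35 or more in the other 14 tumors, while Krt14, its partner, was 8.12 in 531C and 11.27 in 531B. The red blood cell score was 13.48 in 531A and 11.21 in 525A.

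Genes of antigen presentation followed the interferon genes closely across tumors of a mouse. The MHC class II score went with the MHC class I score (r = 0.958, exact permutation p = 6.03e-06, adjusted p = 3.62e-05, rho = 0.971, exact permutation p = 9.04e-06, adjusted p = 5.43e-05), as did the interferon score (r = 0.948, exact permutation p = 2.11e-05, adjusted p = 6.33e-05, rho = 0.953, exact permutation p = 3.92e-05, adjusted p = 0.000118). Without the 2 farthest tumors r was 0.968 and 0.934, and among the 13 XD libraries 0.935 (exact permutation p = 0.000289) and 0.918 (exact permutation p = 0.000579). Ptprc with MHC class I had rho = 0.776 (exact permutation p = 0.00139, adjusted p = 0.00278), r = 0.687 without the 2 farthest and 0.742 among XD libraries. Interferon with T cell scores had rho = 0.738 (exact permutation p = 0.00401, adjusted p = 0.00602), r = 0.763 without the 2 farthest and 0.652 among XD libraries. The 4 relations named so far kept a permutation p under 0.05 without any 1 of the 16 tumors. The macrophage score had r = 0.624 with MHC class I (exact permutation p = 0.0171, adjusted p = 0.0206, rho = 0.574, exact permutation p = 0.0410, adjusted p = 0.0492), a call that rests on the 2 farthest tumors, among others (r = 0.426 without them, exact permutation p = 0.176). It was 0.626 among XD libraries (exact permutation p = 0.0666), 0.485 without 531C (exact permutation p = 0.0626) and 0.574 without 527B (exact permutation p = 0.0589). The B cell score with MHC class I did not pass (r = 0.267, exact permutation p = 0.410, adjusted p = 0.410, rho = 0.297, exact permutation p = 0.319, adjusted p = 0.319, r = 0.426 without the 2 farthest and 0.303 among XD libraries).

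The skeletal muscle score ranged over 9.88 log2 units between tumors, from 2.33 in 531A to 12.21 in 525B, with Acta1, the muscle actin, from 3.36 in 555C to 14.28 in 555D. Of 10 further muscle genes 9 were measured, and all 9 changed by over 0.5 log2 units per unit of the score (slopes 0.59 to 1.12), with Pvalb listed from 0 to 11.96 and Ttn from 0 to 10.96. Removing the length and GC trend left the range at 0.965 times its value (9.54), which argues against that trend. Muscle carried in with some tumors may therefore account for the range, and no biological explanation was tested.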
